A study of Hypsibius exemplaris with 24 samples.

How the data were processed

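RNA was sequenced from 24 pools of 50 whole *Hypsibius exemplaris*, 3 pools in each of 8 groups: a water control and pools frozen 0, 1, 3, 6, 9, 12 and 24 h after 24 h in 100 µM bleomycin. Per the labels' protocols, total RNA was extracted with a column kit and made into Illumina libraries. The labels give no sequencing batch or date, so no comparison within batches could be made. Groups and replicate numbers were taken from the sample titles, and the columns of the table were matched to samples by the submitters' sample descriptions.

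The deposited values are TPM per transcript, in 1 table for the whole series. Each column sums to the same total within rounding, so the TPM are relative within a library and carry no scaling between libraries. Per the submitters' processing notes, FastQC 0.11.3, Bowtie2 2.2.9, RSEM 1.2.26 and DESeq2 1.22.2 were used, and the notes as used here give no role for each. The genome build and annotation are not given in the sources used here. TPM keeps no sequencing depth, so no counting error or detection limit can be given, and an exact 0 can be a failed estimate as well as absence. For that reason transcripts are described as listed at 0. Isoforms of a locus, and near-identical copies, can share reads that the estimation splits, so values of single isoforms and of members of gene families are uncertain. No pair of libraries held identical values (0 pairs).

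The TPM of each library were divided by its median ratio to the geometric mean, taken over the 12190 transcripts above 0 in all 24 libraries. The scale factors ranged from 0.664 for 12 h replicate 3 to 1.18 for control replicate 3. Transcripts with at least 1 TPM in at least 3 libraries were kept, 16490 of 20853, and log2(scaled TPM + 1) was analysed with limma 3.58.1 in R 4.3.3. Since the table holds no counts, no count model was used. All 24 libraries entered 1 linear model with a mean per group and no other term, so that they share an estimate of the spread. Contrasts were tested with the moderated statistic (eBayes with trend and robust settings), two-sided, with Benjamini-Hochberg adjustment over transcripts within each contrast and a threshold of 0.05. The contrasts were each of the 7 times against control, 24 h against 0 h, and each time against the one before. A moderated F test took the 7 contrasts against control together. An exact permutation test of 3 libraries against 3 cannot give a p below 0.1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

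The groups, tests, alternatives and the rule for named transcripts were fixed before the data were examined, except for the tests and alternatives named below as chosen later. The rule takes, where identifiers have no names, the 2 largest rises and 2 largest falls for each contrast against control and for 24 h against 0 h, by log2 fold change. Such a transcript has an adjusted p under 0.05, a mean of at least 5 scaled TPM in the higher group, and no overlap between the libraries of both groups, which chance gives for 10% of transcripts with 3 libraries against 3. Locus BV898_14257 was named in every group. In addition, 25 lists of genes by function and cell type had been fixed. They match product names, which the table does not pair with its identifiers, so 0 lists matched, and the counts per list, the camera and fry tests and the markers of tissues and food were not used here.

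Overlaps between contrasts that share control libraries were set beside the overlap of independent lists and beside 100 simulations in which residuals were reassigned to unchanged groups. The simulated values for the 134 most risen transcripts at 24 h, for rises at 0 h called lower at 24 h than at 0 h, and for rises at 0 h that were falls at 24 h were added after seeing the data. The procedure was tested on simulated data for 0 h against control over 16490 transcripts. The simulated values were independent and normal, with the same spread in all libraries, as the model assumes. Only transcripts above a minimum mean level were changed. The procedure recovered 43.3% of transcripts changed by 1 on the log2 scale, 85.1% of those changed by 2 and 97.0% of those changed by 4. It made 10 false calls, and 0 calls in a simulated unchanged comparison of 24 h with control. These values do not give the error rate for libraries of uneven spread. The alternatives were unscaled TPM, quantile normalization, other pseudocounts and filters, TPM summed per locus, quality weights per library, the replicate number as a block, the groups compared alone, an added 2-fold threshold, and leaving out each library in turn.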

Results

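RNA from whole *Hypsibius exemplaris*, a freshwater tardigrade, was sequenced after exposure to bleomycin, a drug that breaks DNA strands. Pools of 50 animals spent 24 h in 100 µM bleomycin or in mineral water alone. The control pools and a first set of treated pools were frozen at the end of the exposure, which is 0 h. The other treated pools were washed, moved to agar plates with the green alga *Chlorella* as food, kept at 18 °C and frozen 1, 3, 6, 9, 12 and 24 h later. Each of the 8 groups held 3 libraries, described by the submitters as biological replicates, which gave 24 libraries. The control was taken once, so only 0 h against control compares pools with the same handling. From 1 h on, each contrast with the control also holds the wash, the plates, the food and the time since the control was taken.

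Levels were given as TPM, the share of a library's transcripts that is of 1 kind after correction for length, for 20853 transcripts of 19939 loci. Between 14984 and 17173 transcripts were listed above 0 in a library. TPM keeps no record of sequencing depth, so the depth of each library is unknown. Pearson correlations across transcripts, which are not independent replicates, were 0.898 to 0.960 between the control libraries and 0.929 to 0.946 between the 0 h libraries. They were 0.961 to 0.963 at 1 h, 0.933 to 0.941 at 12 h and 0.937 to 0.968 at 24 h. Levels below are scaled TPM, the deposited TPM divided by a scale factor per library. Fold changes are differences of mean log2(scaled TPM + 1), which understate the change of transcripts with low levels. The deposited table does not pair its transcript identifiers with gene names, so transcripts are given by identifier and described by their level over time.

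The first comparison asked which transcripts differed at the end of the exposure. The largest rise was that of BV898_10457, which was at 1.04 scaled TPM in control replicate 1, was listed at 0 in the other control libraries, and reached 379 ± 84.7 (SD, n = 3) at 0 h. Its log2 fold change was 8.20 with a standard error of 0.34 (limma, adjusted p = 5.08e-13, higher in 3 of 3 libraries). For transcripts taken by the rule for named transcripts, which allows no overlap between groups, counts of 3 of 3 were fixed by the choice. They add no support there. BV898_20063 was at 0.855 in control replicate 1 and listed at 0 in the other controls, and rose to 151 ± 46.9 (SD, n = 3), a log2 fold change of 6.91. Locus BV898_14257 had been chosen before the data were examined because it was recalled from outside the table as a locus that responds to DNA damage, an identity not checked here, so its rise is not independent of that choice. It rose from 12.6 ± 3.38 to 302 ± 110 (SD, n = 3), a ratio of means of 23.9 and a log2 fold change of 4.43 with a standard error of 0.30 (limma, adjusted p = 1.22e-09, higher in 3 of 3 libraries). The largest fall was that of BV898_01325, from 252 ± 153 to 1.56 ± 1.23 (SD, n = 3), a log2 fold change of -6.59 (limma, adjusted p = 4.07e-08, lower in 3 of 3 libraries). BV898_17655 was at 263, 4.95 and 543 scaled TPM in control replicates 1 to 3 and was listed at 0 in all 3 libraries of 0 h (limma, adjusted p = 7.65e-04). Fitted to the 6 libraries of these groups alone, the adjusted p of BV898_17655 was 0.0978.

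Of 16490 transcripts tested, 1298 (7.87%) had an adjusted p under 0.05 at 0 h, 619 higher and 679 lower than in the control. The risen transcripts had a median log2 fold change of 1.26 and the fallen ones of -1.50. At least 4-fold rises numbered 134 and at least 4-fold falls 204, and at least 16-fold changes numbered 30 up and 42 down. The 619 risen transcripts together held 4.51% ± 0.0912 of all TPM in the control and 10.6% ± 0.475 at 0 h (SD, n = 3). The count of 1298 was 618 without control replicate 1, 694 without control replicate 3, 745 without 0 h replicate 2 and 706 without 0 h replicate 3. It was 684 when only the 6 libraries were fitted, 468 higher and 216 lower, and 4811 when libraries were weighted by their quality. Quantile normalization turned the split, with 796 higher and 631 lower. Control replicate 2 itself held much of the large falls: over 247 transcripts that fell at least 8-fold at 0 h when it was left out, the median share of the fall present in it was 1 (quartiles 0.672 and 1.05).

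**Figure D1:**
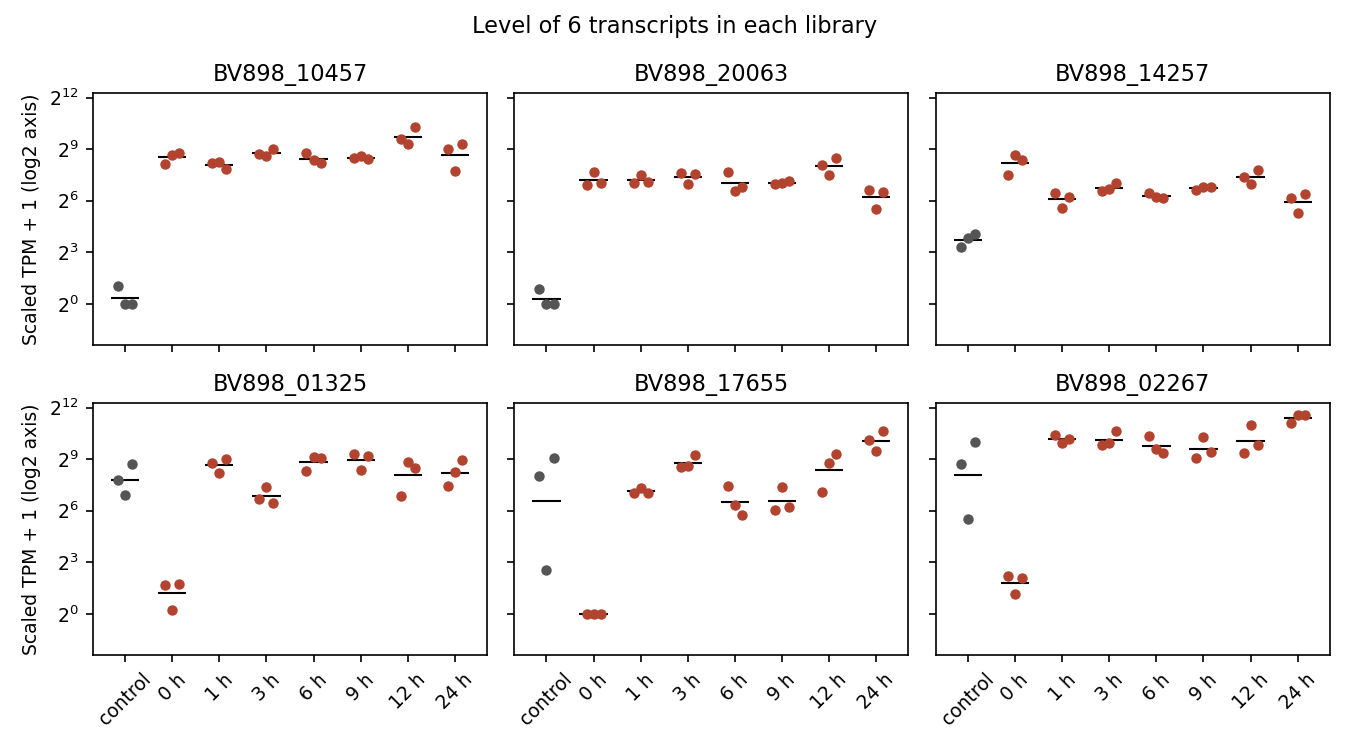
Level of 6 transcripts in each library, as scaled TPM + 1 on a log2 axis, by group on the horizontal axis. Each point is 1 library and each line the mean of the plotted log2 values of a group, with 3 libraries per group; BV898_10457, BV898_20063 and BV898_14257 lie higher in all 21 bleomycin libraries than in the controls, and BV898_01325, BV898_17655 and BV898_02267 lie lowest at 0 h.

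BV898_10457 and BV898_14257 were called higher than control at each of the 7 times. As a set, the 134 transcripts with at least a 4-fold rise held 0.320% ± 0.0289 of all TPM in the control, 2.58% ± 0.138 at 0 h and 1.57% ± 0.286 at 24 h (SD, n = 3). Their median log2 fold change against control was 2.77 at 0 h, 2.45 at 1 h, 2.69 at 3 h, 2.42 at 6 h, 2.37 at 9 h, 2.61 at 12 h and 2.30 at 24 h. The set was chosen on its rise at 0 h against the same control libraries. In 100 simulations of unchanged groups, the 134 transcripts with the highest moderated statistic at 0 h were taken, without the 4-fold threshold. Their median log2 fold change at 24 h was 0.50 (-0.02 to 1.00), against the observed 2.30. Since the simulated sets had no fold threshold to pass, their smaller median does not by itself set the rise at 24 h apart from the choice of the set. The ratio of the median at 24 h to that at 0 h was 0.831, within its simulated range (median 0.506, -0.0248 to 0.921). By library the set median lay between 2.18 and 2.99 above the control mean in the 21 bleomycin libraries, and between -0.09 and 0.04 in the controls. BV898_10457 had the largest rise at each of the 7 times among transcripts meeting the rule for named transcripts, with 884 ± 334 at 12 h and 449 ± 215 at 24 h (SD, n = 3). BV898_04740, at most 0.953 in any control library, was at 133 ± 32.9 at 0 h, 343 ± 103 at 3 h, 405 ± 119 at 12 h and 383 ± 182 at 24 h (SD, n = 3). BV898_14257 was at 68.7 ± 19.5 at 1 h, 108 ± 18.6 at 3 h, 77.4 ± 9.60 at 6 h, 105 ± 6.38 at 9 h, 170 ± 46.1 at 12 h and 64.0 ± 22.7 at 24 h (SD, n = 3), and was called higher than control at each of these times. The 12 h libraries had the lowest scale factors, 0.796 ± 0.114 against 1.04 ± 0.0329 at 9 h (SD, n = 3), which raises their scaled levels. In deposited TPM, replicates 1 to 3 of BV898_04740 were at 301, 280 and 476 at 3 h and 278, 302 and 360 at 12 h. Those of BV898_14257 were at 98.0, 116 and 113 at 9 h and 141.5, 109 and 145 at 12 h. How far the higher levels at 12 h come from the scaling is therefore open.

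The transcripts that fell most at 0 h lay near the control mean at 1 h by their median. The 204 transcripts with at least a 4-fold fall had a median log2 fold change of -2.89 at 0 h, -0.15 at 1 h, 0.06 at 3 h, -0.36 at 6 h, -0.40 at 9 h, -0.33 at 12 h and 0.95 at 24 h. They held 1.83% ± 1.18 of all TPM in the control, 0.118% ± 0.0392 at 0 h, 2.41% ± 0.286 at 1 h, 1.26% ± 0.622 at 12 h and 3.39% ± 0.813 at 24 h (SD, n = 3). The controls were themselves far apart on this set, with medians of 0.44, -1.56 and 1.07 on the log2 scale around the control mean in replicates 1, 2 and 3. The set was chosen on its low levels at 0 h, so levels nearer the control at other times follow in part from that choice. BV898_01325 was at 411 ± 112 at 1 h, 119 ± 42.6 at 3 h and 325 ± 163 at 24 h (SD, n = 3).

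**Figure D2:**
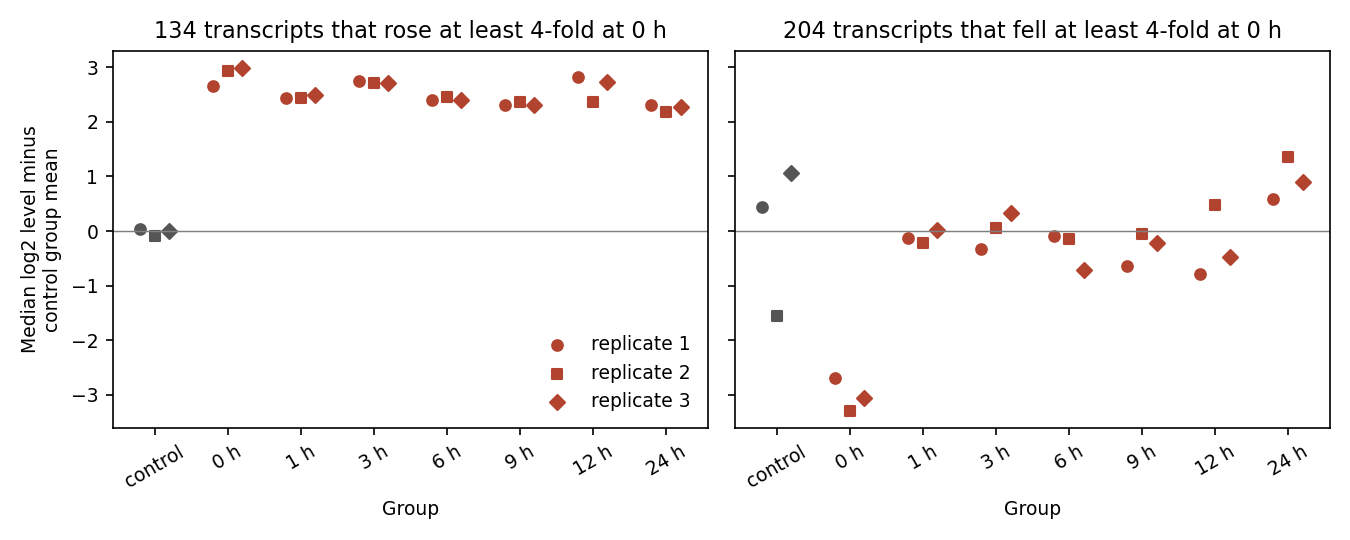
Median log2 level minus the control group mean, in each library, for the 134 transcripts that rose at least 4-fold at 0 h and the 204 that fell at least 4-fold, by group. Each point is 1 library and its shape the replicate number; the risen set stays above 2 in every bleomycin library, and the fallen set is lowest at 0 h, with control replicate 2 at -1.56.

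The largest falls at the later times were those of other transcripts, some of which were also low at 0 h. BV898_12466 was at 105 ± 5.07 in the control and 97.5 ± 15.6 at 0 h, and fell to 2.05 ± 0.741 at 1 h (SD, n = 3), a log2 fold change of -5.15 against control (limma, adjusted p = 2.85e-06, lower in 3 of 3 libraries). BV898_17048 was at 84.4 ± 11.5 in the control, 48.2 ± 13.9 at 0 h and 1.46 ± 0.304 at 1 h (SD, n = 3). At 24 h it was at 71.1 ± 31.2 (SD, n = 3). At 3 h the largest falls were those of BV898_14783, listed at 0 in replicates 1 and 2 and at 12.0 in replicate 3, and of BV898_15348, at 2.83, 0 and 27.3. BV898_14783 was at 49.4 ± 2.64 in the control and 11.2 ± 5.54 at 0 h (SD, n = 3). Without 3 h replicate 1 their adjusted p became 0.0513 and 0.0544, and that of BV898_15348 became 0.0855 without 3 h replicate 2 and 0.0627 with a pseudocount of 0.1. At 6 h they were those of BV898_18341, listed at 0 in all 3 libraries, and BV898_18342, but the controls ranged from 2.29 to 251 and from 1.18 to 381, and at 0 h neither was above 3.06 in any library. With the 6 libraries alone their adjusted p at 6 h was 0.0869 and 0.169, and that of BV898_18341 at 9 h, where it was again listed at 0, was 0.0716. BV898_00251, in its transcript t02, was at 14.1 or more in every control library and listed at 0 in all libraries of 0, 1, 6, 9 and 12 h. At 12 h BV898_13381 was at 4.82, 5.92 and 0 against 164 ± 45.2 (SD, n = 3) in the control, and BV898_00015 at 0, 6.80 and 0 against 103 ± 32.5 (SD, n = 3). At 24 h BV898_11588 had fallen from 102 ± 41.9 to 2.27 ± 0.977 and BV898_04654, in its transcript t02, from 672 ± 240 to 45.6 ± 47.0 (SD, n = 3). Most of these falls began earlier. BV898_11588 was at 39.1 ± 1.60 at 0 h and 9.77 ± 1.74 at 1 h (SD, n = 3). At 1 h BV898_13381 was at 37.1 ± 13.7 and BV898_04654 at 223 ± 36.3 (SD, n = 3). BV898_00015 was at 71.9, 6.04 and 0 in replicates 1 to 3 of 0 h. It was at 33.5 ± 3.93 at 3 h, 34.1 ± 30.1 at 6 h and, higher again, 82.2 ± 45.1 at 9 h (SD, n = 3).

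Against the same control, 3052 transcripts changed at 1 h (1559 higher, 1493 lower), 5293 at 3 h (2701 and 2592), 3376 at 6 h (1794 and 1582) and 4059 at 9 h (2157 and 1902). At 12 h 8229 changed (4124 and 4105) and at 24 h 7775 (4149 and 3626). With TPM left unscaled the split into higher and lower became 2125 and 3111 at 3 h, 1764 and 2419 at 9 h, 2596 and 5869 at 12 h, and 3164 and 4577 at 24 h. Leaving TPM unscaled shifted the log2 fold changes of the transcripts by a median of -0.16 at 3 h, -0.12 at 6 h, -0.15 at 9 h, -0.50 at 12 h and -0.28 at 24 h. Directions here are therefore relative to the median transcript. Unscaled TPM also turned the split at 1 h, to 1299 higher and 1684 lower, and at 6 h, to 1495 and 1897. With quality weights the counts at 1, 3, 6 and 9 h were 8050, 8352, 7309 and 7873, and those at 12 and 24 h were 9398 and 11168. The order of 12 and 24 h thus turned with the weights. Without 12 h replicate 3 the count at 12 h was 7161, but with fewer libraries than the 7775 at 24 h. These 2 counts therefore do not decide the order. The count at 1 h was 1925 without 1 h replicate 1 and 1937 without control replicate 2, and that at 6 h was 2245 without control replicate 1 and 2214 without control replicate 2. With at least a 2-fold change also required, the counts at 1, 3, 6 and 9 h were 1886, 3312, 1928 and 2396.

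**Figure D3:**
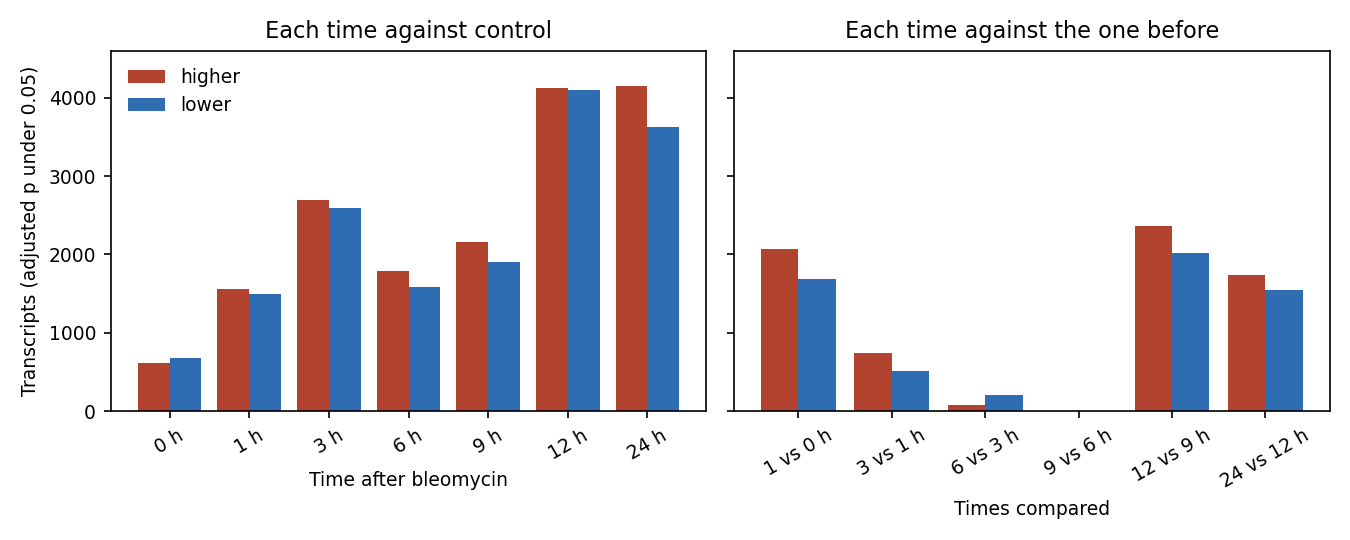
Number of transcripts with an adjusted p under 0.05, higher in red and lower in blue, for each time against control and for each time against the one before. Bars start at 0; the counts were 4124 higher and 4105 lower at 12 h and 4149 and 3626 at 24 h, an order that turned with quality weights, and no transcript passed between 6 and 9 h.

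Over all 8 groups together, the moderated F test called 11085 of 16490 transcripts (67.2%). Among these, the highest group mean fell at 12 h for 2647, in the control for 2380, at 24 h for 2291 and at 0 h for 1553, and at 9 h for only 303. The lowest mean fell at 12 h for 2489, in the control for 2387 and at 0 h for 2294. These places were counted with the main scaling only, and unscaled TPM shifted the log2 fold changes at 12 h by a median of -0.50. At none of the 7 times was a change against control called for 5074 transcripts.

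Consecutive times show when levels moved without use of the control. Between 0 and 1 h 3759 transcripts changed (2070 higher, 1689 lower), between 1 and 3 h 1264 (748 and 516), and between 3 and 6 h 283 (78 and 205). Between 6 and 9 h limma called 0 transcripts, with 665 at an unadjusted p under 0.05 where 825 are given by chance. The spread is shared over all 24 libraries, and consecutive times were not refitted with quality weights or with their 6 libraries alone. The count of 0 therefore does not show that levels stood still. Between 9 and 12 h 4385 changed (2369 and 2016) and between 12 and 24 h 3284 (1743 and 1541). The changes between 9 and 12 h were mostly small: 32 rises and 56 falls reached 4-fold, against 478 and 140 between 0 and 1 h. The smallest adjusted p between 9 and 12 h was 0.00659, against 1.87e-08 between 0 and 1 h (limma). The split between 9 and 12 h was 1016 higher and 3812 lower with unscaled TPM and 1540 and 2145 with quantile normalization, and that between 12 and 24 h was 2465 and 892 with unscaled TPM. With at least a 2-fold change also required, 2315 transcripts passed between 0 and 1 h, 716 between 1 and 3 h, 2101 between 9 and 12 h and 1866 between 12 and 24 h. Single libraries moved several counts. That between 1 and 3 h was 803, 582 and 594 without 1 h replicates 1, 2 and 3, and 501 without 3 h replicate 1. That between 3 and 6 h was 88 without 3 h replicate 1, 91 without 6 h replicate 2 and 125 without 6 h replicate 3, and that between 6 and 9 h was 1 without 6 h replicate 1. That between 9 and 12 h was 2395 without 9 h replicate 1, 1928 without 9 h replicate 3 and 978 without 12 h replicate 3. That between 12 and 24 h was 1612 without 12 h replicate 3 and 1698 without 24 h replicate 2.

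The last comparison set 24 h against 0 h, both after bleomycin, of which only the later group had been washed and fed. BV898_02267 rose from 2.69 ± 1.24 to 2758 ± 484 (SD, n = 3), a log2 fold change of 9.60 with a standard error of 0.72 (limma, adjusted p = 2.51e-08, higher in 3 of 3 libraries). It was at 413, 45.5 and 1006 in the controls. BV898_17655, listed at 0 in the libraries of 0 h, was at 1120 ± 435 at 24 h (SD, n = 3). BV898_04554 fell from 584 ± 143 (SD, n = 3) to 20.5, 0 and 40.9 in the 3 replicates of 24 h, below its 80.2 ± 8.75 (SD, n = 3) in the control. BV898_04948 was at 2.35 ± 1.60 in the control, 253 ± 26.6 at 0 h and 10.4 ± 4.61 at 24 h (SD, n = 3). BV898_14257 was lower at 24 h than at 0 h, with a log2 fold change of -2.22 and a standard error of 0.30 (limma, adjusted p = 5.97e-06, lower in 3 of 3 libraries). In all, 7610 transcripts differed between 0 and 24 h, 4090 higher and 3520 lower at 24 h. The split turned under both other scalings, to 3536 higher and 4219 lower with quantile normalization and to 3391 and 4155 with unscaled TPM. Quantile normalization shifted the log2 fold changes of the transcripts by a median of -0.14 and unscaled TPM by a median of -0.19.

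Rises were shared between 0 and 24 h for 382 transcripts and falls for 195. Independent lists of these sizes would share 156 and 149. In 100 simulations of unchanged groups against shared controls, lists of these sizes shared a median of 426 rises (109 to 600) and 420 falls (92 to 587), both medians above the observed overlaps. The simulated lists hold the top ranks of residuals, with no threshold on p, so they need not match the called lists. By this count the overlap of falls may come in part or in whole from the shared controls, which are too few to split. The overlap of rises may also come from them in part or in whole. The rises at all 7 times, given below, lay above all 100 simulations, but they do not decide this. All 7 contrasts share the controls. The simulations also drew on residuals of every group, whereas the controls had the lowest correlation within a group, 0.898. The overlap of rises was 229 without control replicate 1, 245 without 0 h replicate 3, and 248 with at least a 2-fold change required. Rises at all 7 times, which are among the 382, were called for 225 transcripts, where the simulations gave a median of 51 and at most 134, and falls at all 7 times for 69, where they gave 46.5 (5 to 225). Of the 679 transcripts that fell at 0 h, 408 were called higher at 1 h than at 0 h, where independent lists would share 85.2 and simulations gave a median of 302 (47 to 530), a range that holds the observed count. Of the 619 that rose at 0 h, 231 were called lower at 24 h than at 0 h, where independent lists would share 132 and simulations gave a median of 387 and at most 550, a range that holds the observed count.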

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

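The tests of a mislabelled library, of a lower depth of control replicate 2, of food or handling, of scaling, of a single library of a change that goes on to 24 h, and the simulated count of transcripts risen at 0 h and fallen at 24 h, were chosen only after the results were seen.

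The effect against control differed between 0 and 24 h for 7610 transcripts, by the direct test of 24 h against 0 h. Of these, 209 had fallen at 0 h and risen at 24 h, where independent lists would share 171 and simulations of unchanged groups gave a median of 6.5 (0 to 214). Another 27 had risen at 0 h and fallen at 24 h, where independent lists would share 136 and simulations gave a median of 3.5 (0 to 191). Among the named transcripts, the effect of BV898_20063 was lower at 24 h by a log2 difference of -0.99, and those of BV898_04554, BV898_04948 and BV898_14257 by -5.89, -4.55 and -2.22. The effect was higher at 24 h for BV898_01325 by 7.02 and for BV898_02267 by 9.60. BV898_17655 was listed at 0 in every library of 0 h and had a mean of 1120 scaled TPM at 24 h.

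Control replicate 2 lay as close to the 0 h libraries (Pearson r across transcripts 0.907 to 0.933) as to control replicates 1 and 3 (0.922 and 0.898), which correlated at 0.960. A mislabelled 0 h library would carry the bleomycin rises, but over 56 transcripts risen at least 8-fold without it the median share of the rise it held was -0.0163 (quartiles -0.128 and 0.0822), whereas over 247 transcripts fallen at least 8-fold the median share of the fall was 1 (quartiles 0.672 and 1.05). Lower depth would remove mainly rare transcripts, but 57 of the 208 transcripts at least 8-fold lower in it than in both other controls were at 100 scaled TPM or more in those, where the same search gave 0 for control replicates 1 and 3. Expression that depends on food or handling stays open. Of the 208, 21.2% rose between 0 and 1 h, when the animals were washed and fed, against 12.6% of all transcripts. In 1000 random lists matched on level the lowest share was 9.13% and the highest 23.1%. The 21.2% lies near the top of that full range, and its rank among the lists was not computed, so an excess is neither shown nor excluded. The median log2 change of the 208 was 1.99. Their share of TPM went from 0.144% ± 0.0916 at 0 h to 0.838% ± 0.11 at 1 h and 2.80% ± 0.356 at 24 h (SD, n = 3). Without control replicate 2 the calls at 0 h were 607 higher and 1105 lower in place of 619 and 679, so the falls depend on this library more than the rises do.

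No transcript passed between 6 and 9 h and 4385 did between 9 and 12 h. Few of the 4385 changed strongly, with 32 rises and 56 falls of at least 4-fold, against 478 and 140 between 0 and 1 h. The count was 3685 with quantile normalization and 4828 with unscaled TPM, so it does not rest on the main scaling alone. The split turned, however, from 2369 higher and 2016 lower to 1540 and 2145 with quantile normalization and 1016 and 3812 with unscaled TPM. The scale factors were 0.796 ± 0.114 at 12 h and 1.04 ± 0.0329 at 9 h (SD, n = 3). A scaling error at 12 h would itself give calls, so these counts do not decide how far scaling contributes. Low depth at 12 h would act on rare transcripts, but 52.9% of the 3403 transcripts with a mean of at least 50 scaled TPM were called, against 19.8% of the rest. Leaving out 12 h replicate 3 gave 978, so 1 library moved the count strongly without accounting for all of it, and the counts without 9 h replicates 1 and 3 were 2395 and 1928. A change that goes on to 24 h stays open: the median ratio of the change from 6 to 24 h to that from 9 to 12 h was 0.630, within the simulated range up to 0.709, and a batch of the 12 h libraries cannot be told apart from their time.

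Regrouping the 6 libraries of each contrast gives 10 splits, too few for a share under 0.05. With the real count first and the highest of the other splits after it, the counts were 1298 and 49 at 0 h, 3052 and 4 at 1 h, 5293 and 14 at 3 h, 3376 and 24 at 6 h, 4059 and 3 at 9 h, 8229 and 200 at 12 h and 7775 and 1 at 24 h. They were 7610 and 1 for 24 h against 0 h, 3759 and 0 for 1 h against 0 h, 1264 and 0 for 3 h against 1 h, 283 and 1 for 6 h against 3 h, 4385 and 1 for 12 h against 9 h, and 3284 and 4 for 24 h against 12 h. For 9 h against 6 h all 10 splits gave at least the real count of 0, and the highest gave 1. For the F test over all groups, 1 of 100 splits, the real one, reached 11085 and the highest other gave 115. This argues against a random assignment of libraries to groups as the source of that count. It does not separate time from handling or batch, and real group differences widen the spread in the other splits.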

How the results depend on the processing

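Quantile normalization and omission of single libraries for consecutive times, omission of single libraries for the overlap, and the fits of 6 libraries and the 2-fold threshold for named transcripts were chosen after seeing the data. Of 242 counts under an alternative, 204 stayed within 1.5 times the main count and 38 moved further; apart from settings made of fewer libraries or a stricter threshold, the cause was not tested. Of 680 checks of named transcripts, 671 kept direction and call, 9 kept direction but lost the call and 0 reversed, and 34 of 40 named contrasts kept their call throughout. Unknown depth leaves the precision of low values unknown.

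Quality weights gave 4811, 8050, 8352, 7309 and 7873 transcripts at 0, 1, 3, 6 and 9 h. A 2-fold threshold gave 1886, 3312, 1928 and 2396 at 1, 3, 6 and 9 h, 2315 for 1 h against 0 h, 716 for 3 h against 1 h, 2101 for 12 h against 9 h, 1866 for 24 h against 12 h, and 248 shared rises. The 6 libraries alone gave 684 at 0 h.

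Leaving out a library gave 618 to 1712 at 0 h, 1925 to 3376 at 1 h, 3695 to 5366 at 3 h, 2214 to 3613 at 6 h, 2764 to 4150 at 9 h, 7161 to 8035 at 12 h and 6541 to 8002 at 24 h. It gave 6426 to 7731 for 24 h against 0 h, 10541 to 11096 for the F test and 229 to 529 shared rises. For consecutive times it gave 2659 to 3422, 501 to 1381, 88 to 297, 0 to 1, 978 to 4118 and 1612 to 3630. The libraries that moved a count beyond 1.5 times are named with the results.

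Whether libraries with the same replicate number belong together is not settled by their residuals. Of 84 pairs with the same number, 15 had residuals correlated above 0.1, in a range of -0.303 to 0.409. The mean over these 84 pairs was 0.00749 against -0.00364 for other pairs, and 11 of 24 libraries correlated best with their own number. With the replicate number as a block, the count was 1294 at 0 h, 8268 at 12 h, 7807 at 24 h, 7692 for 24 h against 0 h, 11040 for the F test and 405 shared rises, and no count moved by over 1.5 times. Between consecutive times the block gave 3820, 1381, 323, 0, 4574 and 3458, in order of time, each but the 0 above its main count. The alternative of camera with an estimated correlation was not run, since no gene list matched.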

Other observations

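The search for neighbouring loci and for isoforms was set before its result was seen, and the transcripts low in all controls were chosen after their values were seen.

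In 10 transcripts every control library was under 2 scaled TPM and every one of the 21 bleomycin libraries was at 10 or more. These were BV898_10457, BV898_20063 and BV898_04740, described above, and BV898_15545, BV898_19954, BV898_00680, BV898_12219, BV898_12023, BV898_05766 and BV898_19152.

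Transcripts that rose at 0 h lay at loci with consecutive identifier numbers more often than shuffled loci. Among 618 risen loci 93 pairs had consecutive numbers, where 10000 shuffles of the tested loci gave a mean of 20.6 and at most 39. For the 134 with at least a 4-fold rise there were 23 pairs (shuffled mean 0.946, at most 6), and for 678 fallen loci 56 (shuffled mean 24.6, at most 45). As a hypothesis, neighbouring or duplicated loci may respond together. Identifier numbers are taken here to follow position, which the deposited table does not state, and reads shared between similar copies could also give such pairs.

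Isoforms of a locus mostly moved the same way between 0 and 24 h. Of 80 loci with at least 2 called isoforms, 12 (15%) had isoforms moving apart, against 49.7% for random pairs of called transcripts, so isoform switching remains open for those loci.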
